A study of Mus musculus with 66 samples.

How the data were processed

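Mouse embryonic stem cells were studied by RNA-seq and by ChIP-seq, in 66 libraries. The RNA-seq used an E14Tg2a derivative in which auxin degrades the nuclear receptors Esrrb and Nr5a2, in 54 libraries that make 18 groups of 3. The groups are 2 arms, without and with auxin, at 9 stages: asynchronous cells, cells arrested in mitosis, and 7 times after release from the arrest, from 20 to 60 minutes in steps of 10, then 90 and 120 minutes. The arm was taken from the sample titles, because the treatment entry of the labels reads control for every library, those with auxin included. The ChIP-seq used wild-type E14Tg2a cells, in 12 libraries that make 4 groups of 3: input and Nr5a2, in interphase and in mitosis. RNA libraries were depleted of ribosomal RNA and stranded, per the labels' protocols. Nothing says that the 3 libraries of a group came from separate cultures.

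The authors deposited expression as TPM, RNA abundance scaled for gene length and library size, with 1 column per group, so each value is the authors' mean of a group and carries no spread. Of the 246530 values above 0, 246530 gave a whole number at 9 decimals when multiplied by 3, within 0.02 of the last decimal, as a mean of 3 libraries would. STAR, RSEM and DESeq2 are named with the mm10 genome build, per the submitters' processing notes, without versions. Which part of a gene was quantified is not stated. The listed genes sum to 17155 to 49059 TPM per column, far below the total of the unit, and several abundant single-exon genes are not listed. Unspliced RNA would leave such signs, so whether the values are of spliced or unspliced RNA is open, and they are called RNA levels. The depth per library is unknown, since TPM keeps no depth. The same deposited table gives the authors' call for each of its 13957 genes: 1013 lower, 941 higher and 12003 not responsive. The test, the threshold and the stages behind the call are not given in the sources used here, and the call was made on these same samples.

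The authors deposited a single list of Nr5a2 peaks with start, end and 1 of 4 class codes, L, eB, dB or nB. Bowtie2 and MACS2 are named with mm10, per the submitters' processing notes, without versions. The codes are not defined in the sources used here and their meaning was not guessed. The list has no signal per library, so binding in mitosis could not be compared with binding in interphase, and the strongest peaks could not be ranked. Peak coordinates are as the authors' list gives them.

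From the TPM values, log2(TPM + 1) was computed per group, and the difference with auxin minus without auxin was taken at each stage and averaged over the 7 times after release. Differences on this scale understate the change of low genes. Summaries over genes used the 8999 genes with at least 1 TPM in at least 1 of the 18 groups. The planned tests with limma over the libraries could not be run on group means, so no p-value is given for a single gene. In their place stand the authors' calls, the sign of the difference at each of the 7 times after release, and counts of genes with a 1.5-fold difference between arms or a 2-fold difference from mitosis. A sign shared by all 7 times has a chance of 0.78% in each direction where times are independent and the median difference is 0. Shares of genes have 95% Wilson intervals.

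Gene lists were fixed before the data were examined: naive pluripotency, formative and primed pluripotency, primitive endoderm, trophectoderm, mesendoderm and germ layers, the 2-cell-like state, immediate early, mitotic, G1/S, p53 response, heat shock, aryl hydrocarbon receptor, oxidative phosphorylation, glycolysis, cholesterol synthesis, ribosome biogenesis, fibroblast markers and replication-dependent histones. In place of the planned camera test, members called lower or higher were counted against 13548 genes that reach the lowest mean TPM of any called gene, with a two-sided Fisher's exact test and Benjamini-Hochberg adjustment over 36 tests. Each list's median difference was also placed among 10000 random lists of the same size matched on mean TPM in 20 bins. Medians, and counts of members higher or lower, use members of at least 1 TPM. These can be a small part of a list, such as 4 of 18 trophectoderm and 5 of 20 germ layer genes. Lists with fewer than 3 members of at least 1 TPM got no median.

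Peaks were assigned to a gene when they lay within the gene or within 10 kb of either side, using RefSeq gene positions on GRCm38.p6, which were found for 13943 of the 13957 symbols. The planned distance from the transcription start was replaced because the annotation used here has no strand. Calls were compared by two-sided Fisher's exact tests over genes, adjusted over 12 tests, and over 4 tests each for pairs of peak groups and for differences between differences. Genes are not independent replicates, so these tests describe this table.

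Genes named in the text follow a rule fixed before the data were examined. Esrrb, Nr5a2 and the naive pluripotency list are always named. For the average over the release times, the rule takes the 10 largest differences in each direction among called genes with a mean TPM above the median of 2.24 and 1 sign at all 7 times. For asynchronous cells, mitosis and the differences between differences it takes 5 in each direction among called genes above that median, and for 60 minutes against mitosis 10 in each direction with 1 sign at 60, 90 and 120 minutes. The other lists contribute up to 4 members each. The authors' call replaced the adjusted p of the rule, size replaced the smallest p within lists, and predicted genes and pseudogenes were passed over. Genes that the rule names and the text does not are not reported here, though counts and medians of lists include them.

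Several choices were made after the data were seen: the Fisher tests on calls and the random lists, the background of 13548 genes, the form of the 1 TPM filter, the windows around gene bodies, the grouping of genes by span and by peak class, and which list medians and summaries were followed under other settings. Alternatives were quantile normalization, no filter, a pseudocount of 0.1 and peak distances of 1 and 50 kb. Added after the data were seen were centring each stage on its median difference, leaving out the 40 minute or the 30 and 40 minute columns, for named genes each time in turn, other list backgrounds, and distance from gene ends. The sign count was tested on simulated data of 8999 genes with 50 changed genes at each of 4 folds. It gave 1 sign at all 7 times for 48 of 50 genes at a fold of 0.67, 40 of 50 at 1.5, and 154 of 8799 unchanged genes. The simulated noise was independent between stages. In the data the differences had r = 0.541 across genes between 30 and 40 minutes and -0.027 between 20 and 40 minutes. The simulated share of unchanged genes is therefore not a false rate for these data. The planted folds were also larger than most differences here, where 6 genes were 1.5-fold lower and 0 were 1.5-fold higher on average after release. No shift shared by the genes of a stage was simulated. The shares of changed genes found are therefore not a sensitivity for these data. Here 132 of 7381 genes not called were lower and 167 higher at all 7 times. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.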

Results

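RNA was measured in mouse embryonic stem cells that passed from mitosis into interphase with or without auxin-induced degradation of Esrrb and Nr5a2, nuclear receptors of the pluripotency network. Each of the 18 groups had 3 libraries, and expression is the authors' mean TPM per group, so no value has a replicate error and no single gene has a test. The depth per library is unknown, and so is whether the values count spliced or unspliced RNA. Nr5a2 binding was given as 1 list of 35266 peaks from wild-type cells. The TPM total of the listed genes was 17189 in mitosis without auxin, 49059 at 60 minutes after release and 40735 at 120 minutes. With auxin these totals were 17155, 46542 and 41287.

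The first comparison asks which genes return after mitosis in cells that keep both receptors. RNA levels stayed near the mitotic level for 30 minutes (median log2 ratio 0.04 at 20 and -0.01 at 30 minutes) and were higher for most genes by 60 minutes. Of all genes of at least 1 TPM, 68.5% were above mitosis at 40 minutes and 95.4% at 60 minutes. Counts of members above mitosis at 60 minutes therefore do not set a list apart. Immediate early genes, the first to answer growth signals, had the highest list median at 40 minutes. This median log2 ratio to mitosis was 1.13 at 40 minutes, above all 10000 random lists of matched expression (random median 0.12). All 12 members of at least 1 TPM were higher. The fixed list has 29 genes, of which 17 have values here. Genes of the p53 response had higher medians than immediate early genes at 20 minutes (0.22 and 0.17) and 30 minutes (0.35 and 0.29), were at 1.05 at 40 minutes, also above all random lists, and had the highest list median at 60 minutes, 2.16, with 16 of 16 members higher (random median 1.11). Ccng1, a p53 target, went from 3.37 TPM in mitosis to 26.7 TPM at 60 minutes, and Bbc3, which promotes apoptosis, from 0.565 to 7.91 TPM. G1/S genes followed with a median of 1.91 and 36 of 36 members higher, above all random lists. Among them Slbp, which binds histone transcripts, went from 2.01 to 24.4 TPM and Gins2, a replication factor, from 1.29 to 13.9 TPM.

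Cholesterol synthesis genes formed a transient wave. At 60 minutes 23 of 23 were above mitosis, as were 95.4% of all genes, with a median of 1.48 at percentile 99.53 of the random lists. At 120 minutes 23 of 23 were lower than at 60 minutes, with a median change of -0.76. The share of all genes lower at 120 than at 60 minutes was not computed. Idi1, an enzyme of isoprenoid synthesis, stood at 1.04 TPM in mitosis, 19.4 TPM at 60 minutes and 5.16 TPM at 120 minutes. Insig1, which retains sterol sensors in the endoplasmic reticulum, stood at 1.64, 24.2 and 4.2 TPM. Of the mitotic genes 37 of 38 were above mitosis at 60 minutes, and 34 of 38 were lower at 120 minutes than at 60 minutes, with a median change of -0.68 (random median -0.23). G1/S genes (-0.61, 31 of 36 lower) and immediate early genes (-0.70, 11 of 12 lower) were also lower at 120 than at 60 minutes, below the central 95% of random lists. Kif20a, a mitotic kinesin, went from 0.649 to 6.96 TPM by 60 minutes and stood at 3.35 TPM at 120 minutes.

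**Figure D1:**
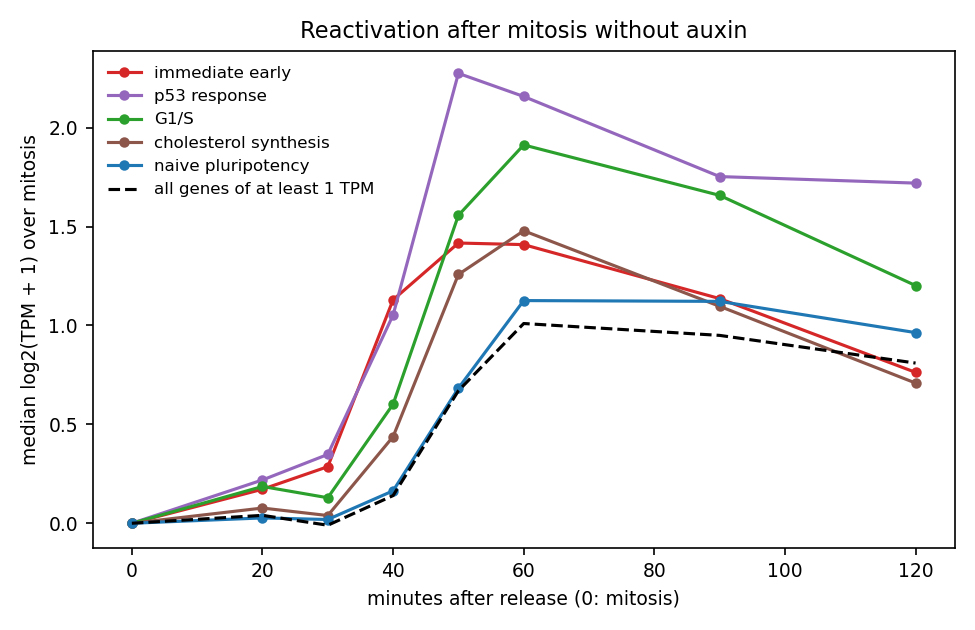
Median log2(TPM + 1) relative to mitosis (vertical axis) against minutes after release (horizontal axis) without auxin, for 5 fixed gene lists and, dashed, for all genes of at least 1 TPM. The p53 response list reaches 2.16 at 60 minutes where all genes have a median of 1.01, and the naive pluripotency list is at 1.13.

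Naive pluripotency genes lay within the central 95% of random lists from 30 to 120 minutes, but below it at 20 minutes (0.03, random median 0.07) and above it in asynchronous cells relative to mitosis (0.63, random median 0.33). Their median at 60 minutes was 1.13, at percentile 39.94 of the random lists, and 37 of 38 were above mitosis. Klf2, a pluripotency transcription factor, had a log2 ratio of 2.10 at 60 minutes and Mycn, a growth regulator, 2.5. Tdh, an enzyme of threonine use, had 0.10, and Manba, a lysosomal enzyme, -0.04. The other lists had medians at 60 minutes of 1.43 for heat shock, 1.42 for ribosome biogenesis, 1.27 for oxidative phosphorylation, 1.26 for glycolysis, 0.93 for formative and primed pluripotency, 0.90 for germ layers, 0.66 for trophectoderm and 0.52 for primitive endoderm, each within the central 95% of its random lists. The 3 aryl hydrocarbon receptor genes had a median of 1.87 at percentile 95.09. Dnajb1, a chaperone, went from 1.55 to 11.9 TPM, Gnl3, a nucleolar protein, from 4.83 to 35.6 TPM, and Nfe2l2, a regulator of the oxidative stress response, from 2.47 to 16.4 TPM. Hist1h2bc, the single member of the fixed histone list in the table, went from 0.681 to 8.41 TPM, and Fn1, an extracellular matrix gene of the fibroblast list, from 4.13 to 11.3 TPM.

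High ratios at 60 minutes among the genes named by rule were in Mir20a, a microRNA gene listed at 0 in mitosis and at 20.0 TPM at 60 minutes, in Cd68, a lysosomal membrane protein, from 1.11 to 22.4 TPM, and in Peg3, an imprinted gene, from 0.340 to 13.0 TPM. Dnajb14, a co-chaperone, had a log2 ratio of 3.35, Atp1b1, a sodium pump subunit, 3.32, and Irs2, an insulin signalling adaptor, 3.31. Rps12 at 3.69 and Hist1h2br at 3.47 have close copies in the genome, so their values are uncertain. The lowest ratios were small in size: Hmces, a sensor of abasic DNA sites, at -0.45, Adam23 at -0.41, Gli2, a Hedgehog effector, at -0.39, Slc9a8 at -0.38, Thada at -0.38, Atf7ip2 at -0.33, Snd1 at -0.31, Insl3 at -0.30, Stmn2 at -0.28 and Macf1, a cytoskeletal linker, at -0.27.

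Counted over 8999 genes, 516 were at least 2-fold above mitosis at 40 minutes, 2752 at 50 minutes, 4569 (50.8%) at 60 minutes, 4043 at 90 minutes and 2975 at 120 minutes. The highest level was reached at 60 minutes by 4105 genes, at 90 minutes by 2120 and at 120 minutes by 2045. With auxin these counts were 3312, 2724 and 2189, a difference that was not tested. With auxin 4208 genes were at least 2-fold above mitosis at 60 minutes, and the log2 ratios at 60 minutes without and with auxin had r = 0.979 and rho = 0.98 across genes, which are not independent replicates. The median over genes was 1.01 above mitosis at 60 minutes, a shift that quantile normalization removes, leaving 463 genes at least 2-fold above mitosis at 60 minutes. It also moves the genes highest at 60 minutes from 4105 to 1139. A pseudocount of 0.1 moved the count at 120 minutes from 2975 to 6100, and without a filter 4083 genes were highest at 120 minutes.

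Timing differed with the span of the gene, a grouping chosen after the data were seen. In the group of genes with the shortest spans, 1 of 5 groups of 1798 genes, the median span was 4615 bp, and in the group with the longest spans 95151 bp. At 40 minutes the median log2 ratio to mitosis was 0.49 in the shortest group and -0.09 in the longest. From 60 to 120 minutes the median change was -0.30 in the shortest and 0.15 in the longest group without auxin, and -0.26 and 0.25 with auxin. The highest level came at 120 minutes for 16.2% of the shortest and 37.5% of the longest genes. The longest group held 324 of the genes called higher with auxin in the authors' deposited table, and the shortest 76. Genes called lower numbered 217 in the longest and 190 in the shortest group.

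**Figure D2:**
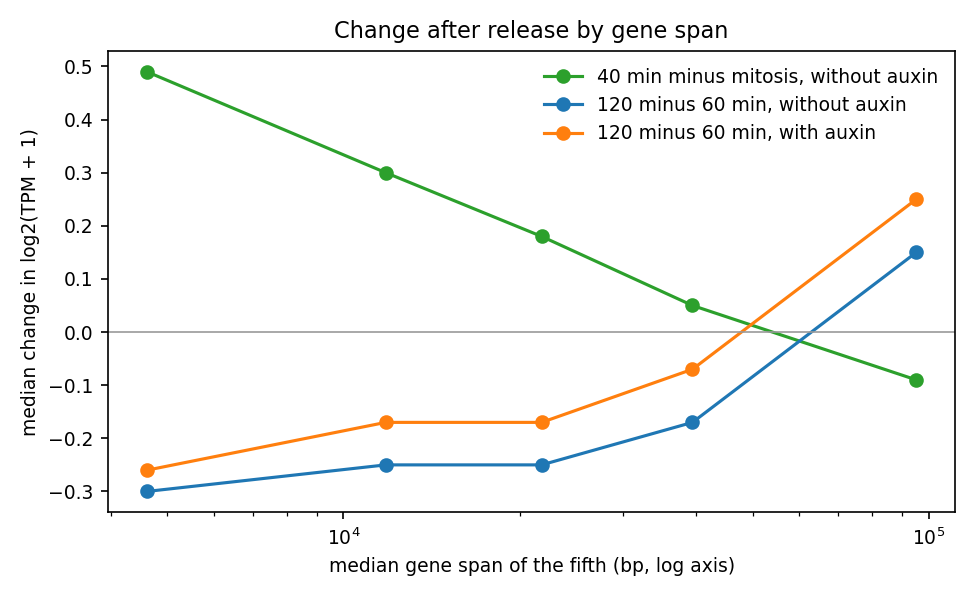
Median change in log2(TPM + 1) (vertical axis) against the median gene span in bp on a log axis (horizontal axis) for 5 groups of genes, from mitosis to 40 minutes without auxin and from 60 to 120 minutes in both arms. The early change drops from 0.49 to -0.09 with span, and the later change without auxin goes from -0.30 to 0.15.

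The next comparison asks how RNA levels after release differed with auxin. No RNA library came from cells given auxin without the degradable receptors, and both receptors are degraded together. Effects of auxin itself, of Esrrb loss and of Nr5a2 loss therefore cannot be told apart. Naive pluripotency genes were lower with auxin. Of the 40 listed, 30 were called lower and 1, Lin28a, a translational regulator, was called higher in the authors' deposited table (Fisher's exact test, odds ratio 38.2, 95% interval 18.1 to 87.9, adjusted p = 1.61e-24). Their median difference over the 7 times was -0.19, below all 10000 random lists, whose median was 0.02, and 33 of 38 members were lower. Jam2, a cell adhesion protein, had a mean over the release times of 4.47 TPM without auxin and 2.15 TPM with auxin. The transcription factor genes Tfcp2l1 (2.43 and 1.28 TPM), Nanog (4.24 and 2.87 TPM), Tbx3 (2.30 and 1.45 TPM) and Zfp42 (35.2 and 26.7 TPM) were lower at all 7 times. Because the calls were made on these samples, they are not independent evidence of the direction. Which stages they rest on is not given, so they are not calls of an effect after release alone. Over all genes of at least 1 TPM called lower, the median difference was -0.195 in asynchronous cells and -0.107 after release.

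The targeted genes themselves, whose proteins auxin degrades, had a mean after release of 4.02 TPM without and 3.65 TPM with auxin for Esrrb, and of 3.92 and 3.58 TPM for Nr5a2. Esrrb was lower at 7 of 7 times and Nr5a2 at 5 of 7, where its log2 difference of -0.06 ranged from -0.10 to -0.02 when single times were left out. These RNA levels do not measure the protein, so they do not check the degradation. Further naive genes below the arm without auxin after release were Dppa5a (-0.53), Utf1 (-0.50), Tdh (-0.43), Tcl1 (-0.40), Nr0b1 (-0.39), Tdgf1 (-0.34), Mybl2 (-0.33) and Klf2 (-0.32). Manba (-0.26), Ooep, Klf5, Klf4, Socs3, Mycn, Pou5f1, Spp1, Fgf4, Lifr, Tet2, Fbxo15 and Il6st (-0.13) followed. The differences of Prdm14, Trim28, Sall4, Myc, Dppa2 and Dppa4 lay from -0.09 to -0.03, and those of Rif1, Lin28a, Stat3, Dppa3 and Gbx2 from 0.02 to 0.09, where the sign of Rif1 turned under quantile normalization and without the 40 minute columns. Of these, Socs3, Myc, Dppa2, Dppa4, Rif1, Stat3, Dppa3 and Gbx2 were not called.

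**Figure D3:**
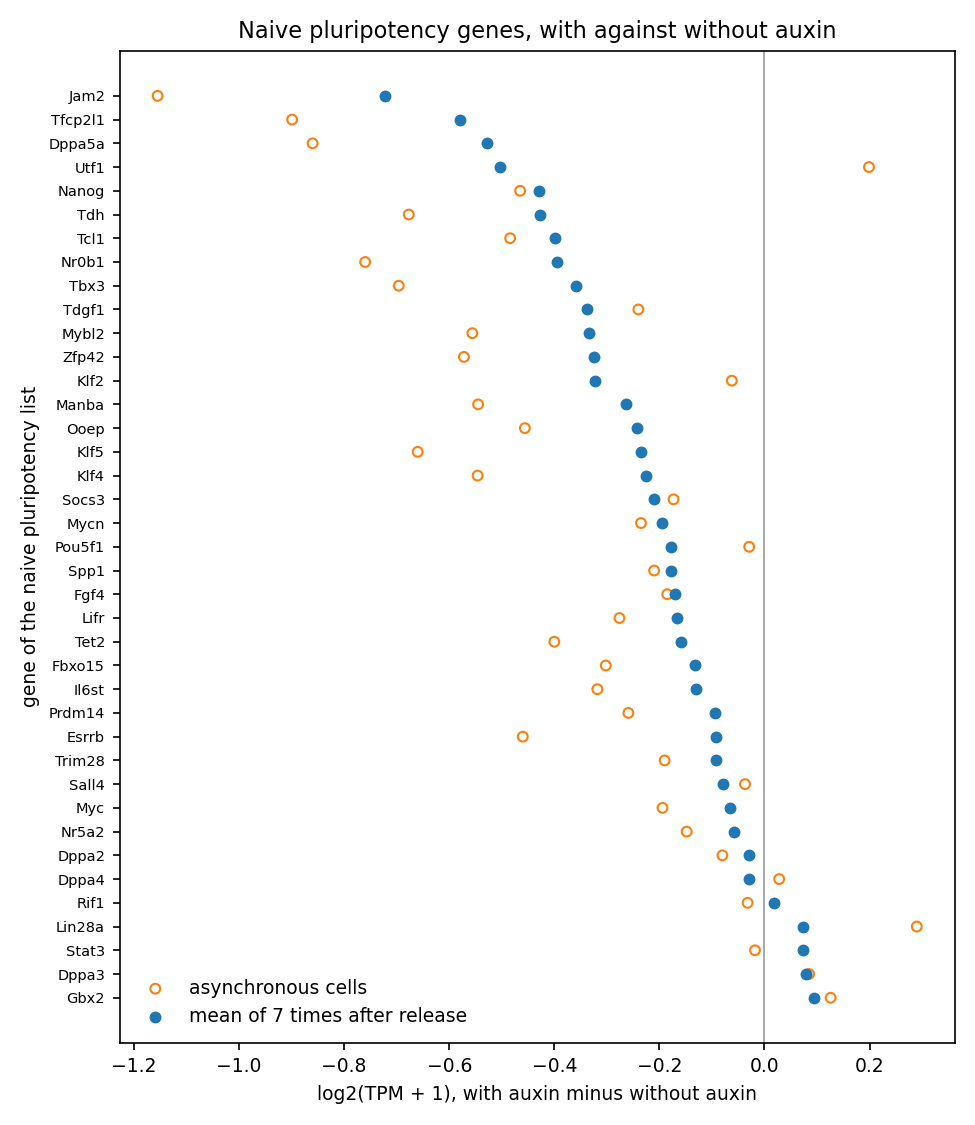
Difference in log2(TPM + 1), with auxin minus without auxin (horizontal axis), for genes of the naive pluripotency list (vertical axis), as the mean of 7 times after release (filled) and in asynchronous cells (open), from the authors' means. Jam2 is lowest at -0.72 after release and -1.16 in asynchronous cells, and the open points of Klf2, Pou5f1, Sall4, Stat3 and Rif1 and the filled point of Rif1 turn sign under quantile normalization.

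Among the genes called lower with the largest differences after release were also Ntn1, an axon guidance cue (5.23 and 2.95 TPM), Fabp3, a fatty acid carrier (4.58 and 2.30 TPM), Ldhb, a lactate dehydrogenase (4.33 and 2.33 TPM), and Zc3h12a, an RNase that degrades inflammatory transcripts (3.51 and 2.23 TPM). Nid2, a basement membrane protein, stood at 5.25 and 3.43 TPM, Zfp57, which protects imprints, at 9.76 and 6.5 TPM, Triml2 at 12.8 and 8.88 TPM, and Igfbp2, which binds insulin-like growth factors, at 5.38 and 3.70 TPM. Genes called higher had smaller differences. Crebzf, a transcription cofactor, led them at 21 TPM without and 26.3 TPM with auxin. It was followed by Cth, an enzyme of cysteine synthesis (2.74 and 3.24 TPM), Cox18 (2.25 and 2.75 TPM), the Notch ligand Dll1 (2.83 and 3.37 TPM), G2e3 (2.28 and 2.75 TPM) and the ion carrier Slc12a2 (3.0 and 3.52 TPM). The p53 regulator Mdm4 (14.6 and 16.7 TPM), the receptor inhibitor Errfi1 (4.99 and 5.87 TPM) and Nufip2 (19.5 and 22.1 TPM) were also among them.

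Glycolysis genes were called lower for 6 of 20 members in the authors' deposited table (odds ratio 5.33, adjusted p = 0.0322). These included Pdk1, which restrains pyruvate oxidation (2.72 and 1.97 TPM), the glucose carrier Slc2a1 (10.3 and 8.27 TPM), Gpi1 (6.56 and 5.40 TPM) and Pfkp (1.05 and 0.756 TPM), and 17 of 18 members were lower. Formative genes were called lower for 6 of 19 members (odds ratio 5.74, adjusted p = 0.0322), among them the FGF signalling genes Spry4 (13.8 and 11.1 TPM), Etv5 (10.5 and 8.85 TPM) and Etv4 (2.33 and 1.95 TPM), and Tcf15 (8.30 and 6.70 TPM). The formative median was -0.06 and turned to 0.001 without the filter. The p53 response had 5 of 17 members called higher (odds ratio 5.61, adjusted p = 0.044), including Ccng1 (19.2 and 21.3 TPM), Eda2r (8.66 and 9.38 TPM), Perp (0.726 and 0.951 TPM) and Rrm2b (0.628 and 0.713 TPM), while the list's median difference was 0.00, with 8 members higher and 8 lower. Without 40 minutes the log2 difference went from 0.17 to 0.10 for Ccng1 and from 0.13 to 0.08 for Eda2r. Against genes of at least 1 TPM the adjusted p became 0.0578 for glycolysis, 0.0611 for the formative list and 0.0631 for the p53 response, so these 3 calls depend on the background.

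The remaining lists did not pass the test on calls, although the medians of oxidative phosphorylation (-0.02, 33 members), trophectoderm (-0.12, 4 members) and germ layer genes (-0.10, 5 members) lay below the central 95% of their random lists. Oxidative phosphorylation had 7 of 34 members called lower (adjusted p = 0.0835), among them Cox5a (5.97 and 5.01 TPM) and Cox4i1 (19.3 and 17.0 TPM). Trophectoderm had 3 of 12 (adjusted p = 0.283), with Tfap2c at 2.58 and 1.73 TPM, and fibroblast markers 2 of 5 (adjusted p = 0.283). G1/S had 5 of 37 called lower, with Mcm7 at 18.5 and 16.1 TPM and the cyclin Ccnd1 at 3.06 and 2.60 TPM. Called lower were also 3 of 38 mitotic genes, 2 of 14 germ layer genes, 1 of 12 primitive endoderm genes, 1 of 5 genes of the 2-cell-like state and 1 of 27 ribosome biogenesis genes, which was Ubtf (6.32 and 5.04 TPM). Called higher were 2 of 19 formative, 2 of 12 trophectoderm, 2 of 14 germ layer, 2 of 37 G1/S, 1 of 12 primitive endoderm, 2 of 14 heat shock and 1 of 17 immediate early genes. Some of these calls were not matched by the release means. Zscan4d, the 2-cell-like gene called lower, stood at 0.057 TPM without and 0.058 TPM with auxin. Hspb1, a heat shock gene called higher, stood at 2.34 and 2.31 TPM. Of all called genes, 360 of 1013 called lower and 409 of 941 called higher had a mean under 1 TPM. None of 23 cholesterol synthesis genes, 4 aryl hydrocarbon receptor genes and 1 histone gene was called either way in the authors' deposited table.

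Over all called genes of at least 1 TPM, 832 of 851 called lower in the authors' deposited table were lower on average after release and 348 (40.9%) at all 7 times. Of 767 called higher, 758 were higher on average and 182 (23.7%) at all 7 times. Of 7381 not called, 132 were lower and 167 higher at all 7 times. Differences were small: the median was -0.11 for genes called lower and 0.09 for genes called higher, and 6 genes were 1.5-fold lower and 0 genes 1.5-fold higher on average. With a pseudocount of 0.1 these counts were 33 and 7. Centring each stage on its median raised the genes higher at all 7 times from 182 to 331, and without 30 and 40 minutes 613 genes called lower were lower at all 5 times left, a weaker criterion that can only raise the count.

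By stage, the share of called-lower genes that were lower ranged from 63.8% at 40 minutes to 94.6% in asynchronous cells, and the share of called-higher genes that were higher from 43.3% at 60 minutes to 97.4% at 30 minutes. Genes that were not called shifted too, with a median difference of 0.08 at 40 minutes and -0.06 at 60 minutes. With each stage centred on its median difference, the share lower became 85.2% at 40 minutes and the share higher became 82.9% at 60 minutes, which turns its direction, and quantile normalization gave 80.8% and 80.9%. At single stages 12 genes at 20 minutes to 49 genes at 120 minutes were 1.5-fold lower. From 3 genes in mitosis and at 20 minutes to 20 genes at 40 minutes were 1.5-fold higher. Many of these genes did not carry the matching call. Called lower were 4 of 12 at 20 minutes, 10 of 33 at 40, 11 of 28 at 60 and 36 of 49 at 120 minutes. Called higher were 0 of 3 at 20 minutes, 5 of 20 at 40, 3 of 7 at 60 and 0 of 10 at 90 minutes. A pseudocount of 0.1 moved the counts of 1.5-fold genes to between 80 and 171 lower and between 31 and 120 higher.

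**Figure D4:**
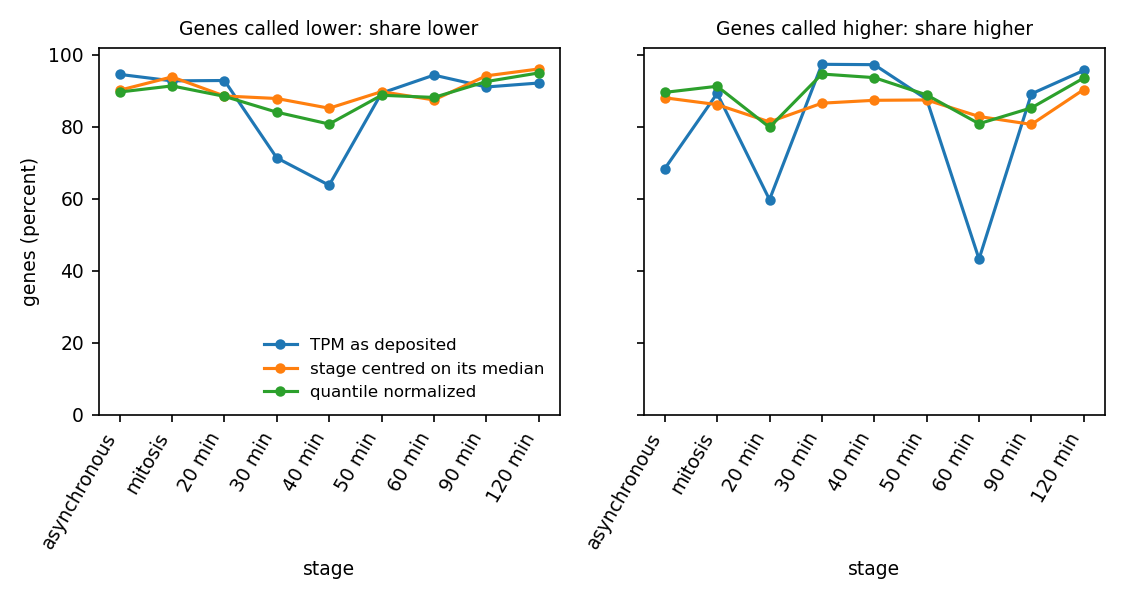
Percent of genes called lower that were lower with auxin (left) and of genes called higher that were higher (right) at each stage (horizontal axis), with TPM as deposited and under 2 other scalings. With TPM as deposited the share higher drops to 43.3% at 60 minutes, while centring gives 82.9%.

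In asynchronous cells, which show whether the same genes differ with auxin without a preceding arrest, naive pluripotency genes were lower with auxin too. Their median difference was -0.26 against -0.04 for the random lists, and 33 of 38 members were lower. Glycolysis genes were lower for 14 of 18 members (median -0.10), where 72.4% of 7381 genes not called were lower. The formative (0.06) and p53 response (0.03) medians lay above the central 95% of their random lists. Ldhb stood at 3.68 TPM without and 0.962 TPM with auxin, Ntn1 at 3.48 and 0.942 TPM, Jam2 at 7.19 and 2.68 TPM, and Fabp3 at 2.47 and 0.637 TPM. Mir298, a microRNA gene called lower, stood at 2.25 and 0.370 TPM. Esrrb stood at 3.86 and 2.53 TPM and Nr5a2 at 3.87 and 3.40 TPM. Among genes called higher, the growth inhibitor Btg1 stood at 1.0 and 1.70 TPM, Zfp428 at 2.77 and 3.93 TPM, the Notch ligand Jag1 at 1.34 and 1.94 TPM, Gadd45b, a stress response gene, at 0.288 and 0.620 TPM, and Skil, a repressor of TGF-beta signalling, at 5.44 and 7.06 TPM. Klf2 (-0.06), Pou5f1 (-0.03) and Sall4 (-0.04) lay near 0 here, and their sign turned under quantile normalization. In asynchronous cells 44 genes were 1.5-fold lower, 42 of them called lower, and 6 genes 1.5-fold higher, 2 of them called higher. Across all 8999 genes, which are not independent replicates, the differences after release and in asynchronous cells had r = 0.472 and rho = 0.343. Across the 1618 called genes they had r = 0.736 and rho = 0.719, where selection by calls on these samples favours a shared sign, and across genes not called r = 0.085 and rho = 0.136.

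In mitotic cells naive pluripotency genes were already lower, with a median difference of -0.10 below all random lists and 26 of 38 members lower. The largest differences among genes called lower were in Snhg15, a noncoding host of small nucleolar RNA (8.34 and 2.58 TPM), Ccdc107 (5.16 and 2.05 TPM), Zfp646 (2.90 and 1.06 TPM) and Utf1, a chromatin factor of stem cells (3.29 and 1.49 TPM). Rps27a, at 3.79 and 2.08 TPM, has processed copies, so its value is uncertain. Those among genes called higher were in Zc3h7a (3.59 and 12.1 TPM), the splicing regulator Raver1 (1.17 and 1.73 TPM), Hax1 (4.02 and 5.19 TPM), Utp14b (1.15 and 1.63 TPM) and Hnrnph2 (1.41 and 1.87 TPM). In mitosis 13 genes were 1.5-fold lower, 7 of them called lower, and 3 genes 1.5-fold higher, 1 of them called higher.

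The effect after release was then set against the effect in mitosis. Dppa5a, a marker of naive cells, differed most among naive genes: with auxin its difference was 0.04 in mitosis and -0.53 after release, a change of -0.57. Fabp3 changed by -0.39, Ifitm1, an interferon-induced membrane protein, by -0.39, and Zfp593 by -0.38, all lower relative to the arm without auxin after release than in mitosis. Snhg15 (0.95), Zfp646 (0.78), Rps27a (0.62), Ccdc107 (0.60) and Terf2ip, a telomere protein (0.47), were on average closer to the arm without auxin after release. Of these, Ccdc107 was lower at all 7 times, and the others at 3 or 4 times, with Snhg15 between -2.32 at 40 minutes and 0.55 at 50 minutes. Zc3h7a changed by -1.02, but its value with auxin was 88.5 TPM at 40 minutes against 4.10 TPM without. When that time is left out, its mean difference after release turns from 0.49 to -0.11 and its change becomes -1.62. Of 851 genes called lower, 60.2% were lower relative to mitosis after release, against 41.9% of genes not called (Fisher's exact test, odds ratio 2.09, 95% interval 1.81 to 2.42, adjusted p = 2.75e-23), though the median change was near 0. The excess was smaller under other settings, 52.5% against 48.5% (odds ratio 1.18) with quantile normalization and 50.8% against 42% (odds ratio 1.42) with a pseudocount of 0.1. The genes were selected by calls made on these same samples.

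Set against asynchronous cells, the differences after release were closer to 0 for Ldhb (change 0.65), Epha4, an ephrin receptor (0.58), and Jam2 (0.43). They were lower after release for Utf1 (change -0.70), Zfp646 (-0.66), Arf6, a trafficking GTPase (-0.52), the kinase gene Pim3 (-0.49) and Adrm1, a proteasome ubiquitin receptor (-0.47). Their differences after release were -0.50, -0.14, -0.20, -0.35 and -0.22 in that order. Each was smaller in size than its change, so these genes, all called lower, were higher with auxin in asynchronous cells. Zfp646 was lower after release at 4 of 7 times, and Arf6 ranged from -1.11 at 40 minutes to 0.64 at 20 minutes. Without 40 minutes the change of Arf6 becomes -0.37 and its difference after release -0.05. Mir298 (1.35), Zc3h7a (0.95) and Rps21 (0.57) also had positive changes, and Rps21 has close copies, so its value is uncertain. Without 40 minutes the change of Zc3h7a becomes 0.34 and that of Mir298 1.11, whose mean difference after release turns from 0.10 to -0.14. The difference was higher after release than in asynchronous cells for 77.6% of genes called lower, 75.2% of genes called higher and 76.7% of genes not called (odds ratio 1.05, adjusted p = 0.607, for genes called lower). With quantile normalization the shares were 66.8% of genes called lower and 50.9% of genes not called, an odds ratio of 1.94, so the comparison depends on the scaling.

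Nr5a2 peaks were then set beside the calls, to ask whether genes called lower or higher with auxin lie near Nr5a2 binding. All 40 naive pluripotency genes had at least 1 peak within the gene or 10 kb of it, 180 distinct peaks in total. Esrrb, on chromosome 12 from 86361117 to 86521628, had 17 peaks, Tfcp2l1 and Sall4 had 10 each, and Jam2, on chromosome 16 from 84774123 to 84826380, had 9, of which 5 had the class dB in the authors' deposited table. A dB peak lay from 122702157 to 122703246 on chromosome 6, 4243 bp from Nanog, and another from 55524782 to 55525370 on chromosome 4, 1767 bp from Klf4. Nr5a2 itself had 5 peaks, 4 of class L and 1 of class eB. Gene positions are on GRCm38 and peaks on mm10, the same build.

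Genes called lower had a peak in 92.6% of 851 cases, genes not called in 70.6% of 7373 (Fisher's exact test, odds ratio 5.21, 95% interval 4.01 to 6.88, adjusted p = 1.44e-51) and genes called higher in 62.4% of 766 (odds ratio 0.691, adjusted p = 6.33e-06). Peaks of class dB were near 42.3% of genes called lower and 16.9% of genes not called (odds ratio 3.60, adjusted p = 3.8e-58). Genes were then grouped by the class of nearby peaks. The groups were not matched on gene span or number of peaks, and genes of the dB group could also have peaks of other classes. Between these groups the share of genes called lower differed. It was 2.5% of 2519 genes without a peak, 5.9% of 2276 with L peaks alone, 11.8% of 2479 with eB or nB but no dB peak, and 21% of 1716 with a dB peak (odds ratio 1.98 against the eB or nB group, adjusted p = 3.18e-15). For genes called higher the shares were 11.4%, 9.4%, 6.3% and 6.3%. Within 1 kb the lower frequency of peaks near genes called higher was no longer past the threshold (odds ratio 0.971). L peaks were then near 38.8% of genes called higher and 34.8% of genes not called (odds ratio 1.19, adjusted p = 0.0494), where within 10 kb the odds ratio was 0.919 (adjusted p = 0.271).

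**Figure D5:**
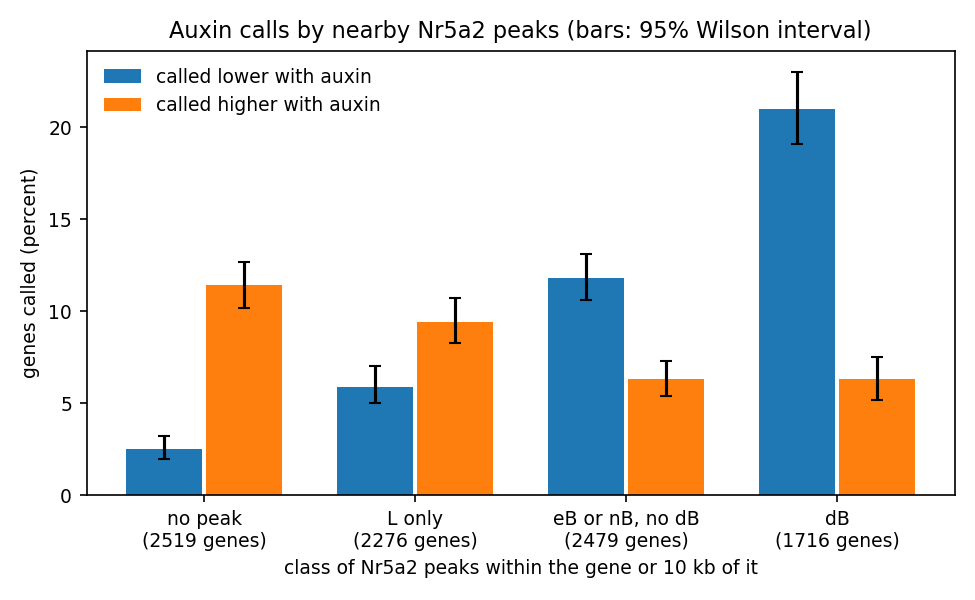
Percent of genes called lower or higher with auxin (vertical axis) by the class of Nr5a2 peaks within the gene or 10 kb of it (horizontal axis), with 95% Wilson intervals as error bars. The share called lower goes from 2.5% without a peak to 21% with a dB peak, in groups not matched on gene span or number of peaks.

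Of the 35266 peaks, 22970 (65.1%) had the class L, 6398 (18.1%) eB, 3621 (10.3%) dB and 2277 (6.5%) nB in the authors' deposited table. Of other lists, which were not tested for peaks, 32 of 34 oxidative phosphorylation, 19 of 20 glycolysis, 17 of 19 formative, 29 of 38 mitotic, 28 of 37 G1/S, 10 of 14 heat shock, 12 of 17 p53 response and 16 of 23 cholesterol synthesis genes had a peak, beside the 70.6% of genes not called. The sets differ: the list counts hold members of any TPM, called or not, and the 70.6% is of genes of at least 1 TPM. How binding differs between interphase and mitosis could not be tested, because the list has no value per library.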

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

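The genes in this part were picked by a rule applied to the group means, and the difference between asynchronous cells and the time after release was not tested for any of them. Each has 1 sign with auxin at all 7 times after release and the opposite sign in asynchronous cells, and each is named in the report. Utf1, a chromatin factor of stem cells, had a log2 difference of 0.20 in asynchronous cells (7.67 TPM without and 8.95 TPM with auxin) and -0.50 after release, where single times ranged from -0.81 to -0.31. Ifitm1, an interferon-induced membrane protein, had 0.10 in asynchronous cells and -0.20 after release. Cth, an enzyme of cysteine synthesis, had -0.22 in asynchronous cells and 0.21 after release. The p53 regulator Mdm4 had -0.007 and 0.18, the receptor inhibitor Errfi1 -0.084 and 0.18, and Hnrnph2, an RNA-binding protein, -0.10 and 0.14. The median difference of all genes in asynchronous cells was -0.04, so values near 0 there depend on the scaling. Among genes of 1 sign at all 7 times, the sign in asynchronous cells was opposite for 8 of 348 genes called lower and 48 of 182 genes called higher in the authors' deposited table.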

How the results depend on the processing

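Of 265 comparisons of summary results with an alternative, 173 kept their direction and their side of the threshold or stayed in range. In range means within 1.5 times the reported value for a count and within its 95% Wilson interval for a share. Of 807 comparisons for single genes named by rule, 789 kept their sign. In 719 the value rounded to 2 decimals was no longer the same, with no upper bound on the size of the change. For example, the change of Zc3h7a from mitosis to release went from -1.02 to -1.62 without 40 minutes. Of the 18 that turned sign, 7 were for Rif1 and Stat3, which are not called and lie near 0. Comparisons without the filter are left out of the gene counts, since a filter cannot move a single gene. Centring, leaving out times (for named genes also each time in turn), other list backgrounds and distance from gene ends were chosen after seeing the data. At an adjusted threshold of 0.01 the glycolysis, formative and p53 response calls would be lost. Not run, because only group means are available, were other count normalizations, other tests, a replicate block, leaving out a library or replicate number, fits on fewer samples, an estimated correlation between genes, a threshold of 0.01 for the gene calls, and all alternatives for binding in mitosis against interphase. No paired analysis was possible because the values are means over libraries. The depth is unknown, so what it limits could not be computed. The cause was not tested for any change given here unless the setting itself shows it.

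Quantile normalization removes the global rise by construction, so genes 2-fold above mitosis went from 2752 to 599 at 50 minutes, 4569 to 463 at 60, 4043 to 245 at 90 and 2975 to 257 at 120 minutes, and genes highest at 60, 90 and 120 minutes became 1139, 885 and 1354. The share of called-lower genes that were lower became 89.7% in asynchronous cells and 88.5%, 84.1%, 80.8%, 88.2% and 95% at 20, 30, 40, 60 and 120 minutes. The share of called-higher genes that were higher became 89.6% in asynchronous cells and 79.9%, 94.7%, 93.7%, 80.9% (from 43.3%, a reversal), 85.3% and 93.6% at 20, 30, 40, 60, 90 and 120 minutes, and 361 were higher at every time. Genes 1.5-fold higher became 13 in asynchronous cells, 10 in mitosis and 18, 11, 3 and 4 at 20, 30, 60 and 90 minutes. Genes 1.5-fold lower became 24 in mitosis and 36, 58, 9 and 13 at 30, 40, 50 and 60 minutes. Against asynchronous cells the share became 66.8% and the odds ratio 1.94 (past the threshold), and against mitosis the share became 52.5%. In asynchronous cells Klf2 became 0.009, Pou5f1 0.021 and Sall4 0.037, each reversed, and after release Zscan4d became -0.005 from 0.002 (reversed).

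Centring each stage on its median gave shares of called-lower genes lower of 90.2% in asynchronous cells and 88.6%, 87.9%, 85.2%, 87.5%, 94.2% and 96.1% at 20, 30, 40, 60, 90 and 120 minutes. Called-higher genes higher were 88.1% in asynchronous cells, 86.2% in mitosis and 81.4%, 86.6%, 87.4%, 82.9% (reversed), 80.7% and 90.4% at 20, 30, 40, 60, 90 and 120 minutes, and 331 were higher at every time. Genes 1.5-fold lower at 40 minutes became 51 and 1.5-fold higher at 90 minutes 6. In asynchronous cells Pou5f1 became 0.01 and Sall4 0.002, both reversed, as was Zscan4d after release (-0.013).

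A pseudocount of 0.1 gives low genes larger log2 differences by construction. Genes 1.5-fold lower became 171 in asynchronous cells, 115 in mitosis, 128, 113, 113, 80, 90, 112 and 129 at the 7 release times in order, and 33 over the release. Genes 1.5-fold higher became 61, 74, 73, 77, 120, 31, 40, 45, 35 and 7 in that order. Genes 2-fold above mitosis became 1541, 4734, 6701 and 6100 at 40, 50, 90 and 120 minutes. The share lower than in mitosis became 50.8%.

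Without the filter 4083 genes were highest at 120 minutes, since more genes were counted, the odds ratio against asynchronous cells became 1.4 (past the threshold), and the formative median became 0.001 (reversed). Without 40 minutes 96.9% of called-higher genes were higher after release, and Zscan4d turned to -0.012. Without 30 and 40 minutes this was 93.1%, and 613 called-lower genes were lower at all 5 times left, a weaker criterion that can only raise the count. Zscan4d (-0.004) and the heat shock genes Hspa8 (-0.007) and Hspb1 (-0.058) then turned sign. Against genes of at least 1 TPM the adjusted p became 0.0578 for glycolysis, 0.0611 for the formative list and 0.0631 for the p53 response, where fewer genes were in the background. For genes called higher, peaks within 1 kb gave odds ratios of 0.971 for any class, 0.872 for eB, dB or nB, and 1.03 for dB (reversed), and for class L 1.19, past the threshold, from 0.919. For dB the odds ratio was 0.642 within 50 kb and 0.555 within 10 kb of either gene end, both past the threshold.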

Other observations

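All tests of explanations in this part had their bounds set before the value was computed; the correlations of gene span with the change up to 40 minutes were looked at only after the result was seen.

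Ribosome biogenesis, oxidative phosphorylation and glycolysis genes differed between 60 and 120 minutes within the central 95% of random lists, with median changes of -0.17, -0.33 and -0.22 without auxin. Ccng1, which encodes a cyclin and is a p53 target, stood at 26.7 TPM at 60 minutes and 28.9 TPM at 120 minutes, and Nip7, a ribosome assembly factor, at 10.1 and 9.92 TPM. Trophectoderm genes were lower with auxin in asynchronous cells for 4 of 4 members (median -0.25) and in mitosis for 4 of 4 (median -0.13). Of genes not called, 72.4% were lower in asynchronous cells and 44.5% in mitosis. Mitotic genes were lower with auxin in asynchronous cells for 35 of 38 members, with a median of -0.09 where random lists had -0.04.

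Most genes shifted upward with auxin at 40 minutes, where the median difference of genes not called was 0.08 and the TPM total 6.8% higher. Whether libraries with auxin were further along the release at 40 minutes was not settled. Over 7381 genes not called, the 40 minute difference had a rho of 0.022 (bootstrap 95% interval 0.0 to 0.045) with the rise from 30 to 50 minutes. This lay on the side of its bound that goes against such a lead. With no bound set, the same rho was -0.386 at 30 minutes (rise from 20 to 40 minutes) and -0.253 at 60 minutes (rise from 50 to 90 minutes). At 30 minutes genes not called were also shifted upward with auxin, with a median of 0.055. A rho near its bound at 40 minutes can therefore hide a positive part. A difference in timing between the arms at 30, 40 or 60 minutes is not excluded. A single scaling factor per column may account for the shared shift at 40 minutes, since the medians of the genes with the largest and the smallest rise differed by 0.004. It was not shown to account for the differences between genes, whose SD of 0.171 was the largest of the 9 stages and which had r = 0.541 and rho = 0.658 with those at 30 minutes across genes, which are not independent replicates. An effect of the receptors at 40 minutes stays open and was not tested.

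Genes called lower had a peak within 10 kb in 92.6% of cases. Longer or more highly expressed genes collecting more peaks does not account for this, since draws of genes not called matched on span and TPM had a central 95% that ended at 75.3%. Gene-dense neighbourhoods do not account for it either, with an end at 73.2% in draws matched on the genes within 50 kb. Whether these genes are direct targets of Nr5a2 was not tested. Esrrb peaks were not used here, and the Nr5a2 peaks are from wild-type cells.

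Longer genes gained TPM later after release. The time needed to transcribe long genes is a candidate explanation that the test did not decide, because rho between span and the change from 60 to 120 minutes was 0.265 without and 0.311 with auxin, and a bound of 0.3 in both arms had been set. Expression level as the cause was also not decided: rho was 0.17 in the highest group of mean TPM and 0.273 and 0.331 in the others. A single scaling factor per column is argued against, since the longest and shortest groups differed by 0.45 in median change. The rho of span with the change from mitosis to 40 minutes was -0.604 without and -0.538 with auxin; whether the values are of unspliced RNA is open, and no difference between the study's groups was tested as an explanation.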
